A study of Mus musculus with 8 samples.

How the data were processed

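Rad21 ChIP-seq was measured in 8 libraries of stimulated AID-deficient CH12F3 cells, 2 for each of 4 genotypes. Per the labels' protocols, chromatin was cross-linked with formaldehyde, sonicated, precipitated with an anti-Rad21 antibody, tagmented on the beads with Tn5 and sequenced as paired ends. The submitters' processing notes name Bowtie2 2.4.4, SAMtools 1.15.1, deepTools 3.5.1, MACS2 2.2.7.1 and the mm9 genome, without settings or order. The peak threshold, the filters on reads and any control library are not given in the sources used here. Each library has its own deposited peak list of 10 columns, so peaks were called per library and not on pooled samples.

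Per peak, the deposited lists give the authors' score, the fold enrichment at the summit as a ratio over the expected background, the −log10 p and −log10 q of the peak caller, and the summit's distance from the peak start. These values belong to each list and were used only to describe, rank or filter peaks within it. The lowest −log10 q in a list was between 1.53 and 2.17. The fold values in the deposited lists rose in equal steps, so that each was (height + 1) over (background + 1) with one expected background per library. All heights came out whole within 0.01, and the Poisson −log10 p computed from height and background differed from the deposited one by a median of under 1e-05 in each list. The background was therefore genome-wide in each list, with no sign of a local or input-based expectation, and it is the only sign of depth in the lists: 0.394, 0.731, 0.293 and 0.223 fragments for FS_Ca replicates 1 and 2 and FS_Ia replicates 1 and 2, and 0.772, 0.587, 0.622 and 0.862 for PS_Ca replicates 1 and 2 and PS_Ia replicates 1 and 2. Duplicate fragments and differences in enrichment also move the number of peaks, and counting error alone is large at summits of 3 to 5 fragments.

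The mm9 build was checked against the positions: each list had peaks on chromosome 1 past the last gene of the only annotation at hand, 85 in all, which is of another build (GRCm38). No coordinates of that annotation were used, no gene was assigned to a region, and the planned test of 11 gene lists was not made. The parts of Igh were approximate mm9 windows set before the data were examined, as were the tests, the alternatives and the rule for named regions. The rule took Igh regions before the VH genes found in at least 2 libraries, the 10 best-ranked regions of all 8 libraries, up to 10 regions per direction for each factor and up to 5 per direction for each genotype pair, best mean percentile rank first. The text gives the leading ones of each. Ranks and folds of a named region were taken over all libraries that held it, also those outside the genotypes compared.

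Peaks of all libraries were merged into regions where they overlapped by at least 1 bp, and a library was present in a region if it had a peak there. Peak numbers were compared by exact two-sided permutation of 4 against 4 libraries (70 assignments), presence at Igh regions by Fisher's exact test with Benjamini-Hochberg adjustment, and genotype similarity by an exact one-sided permutation over the 105 pairings of the libraries. Regions specific to one level of a factor were counted and set against the 35 splits into 4 and 4. The alternatives were a stricter threshold (−log10 q of at least 5), lists cut to the 11288 strongest peaks, regions built from summits ± 100 bp, numbered chromosomes with X and Y only, another overlap measure, presence in the strongest peaks against absence from the full lists, each library left out in turn, and libraries of the same number taken as pairs. Others were chosen after seeing the data: chromosome 12 past the 3' flank left out, only the 3' flank of Igh, Igh lined up (the flank as deposited and the windows from Cμ on after each list's offset), values within the sets of peak-name prefixes, chromosomes 16 and X left out, and overlap coefficients with list length held alike.

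Offsets on chromosome 12 were the shift, up to 150000 bp, that lined up most summit pairs with PS_Ia replicate 1, which with PS_Ca replicate 1 showed no displacement. Partners were summits within 500 bp after the shift. Relative heights were medians within a library over regions found in all 8 libraries, with 95% intervals from 500 bootstrap draws of regions.

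The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data. In simulated lists of 20000 common sites, all 60 planted regions of each orientation were recovered, beside 113 and 31 regions that incomplete detection alone made specific to one orientation. A planted shift was recovered within 33 bp in 100 simulations, and the best offset of unrelated lists matched at most 10% of summits. Summit heights were recovered exactly in 100% of simulated peaks, and 4% of permutation tests without a difference gave p of 0.05 or less.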

Results

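The 8 libraries mapped Rad21, the kleisin subunit of the cohesin ring that extrudes chromatin loops and halts at CTCF-binding elements, in CH12F3 cells. CH12F3 is a mouse B lymphoma line that switches from IgM to IgA when stimulated with anti-CD40, IL4 and TGF-β. All lines lacked AID, the deaminase that starts class switch recombination, so that the chromatin was profiled without AID-initiated breaks. Cells had been stimulated for 3 days. The series asks how chromatin configuration bears on the orientation in which the broken switch regions are joined.

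The design crossed 2 features of the engineered Igh allele. Ca lines, built in cells whose non-coding Igh allele lacks the segment from VH to the 3' CTCF-binding elements, carry Cα in their name. Ia lines, built in αInv cells, carry Iα instead, and this difference is called orientation here. In FS lines the γ3 and α switch regions (Sγ3 and Sα) were kept at full length, and in PS lines only parts of both were kept. This gave 4 genotypes, FS_Ca, FS_Ia, PS_Ca and PS_Ia, with 2 libraries each. The labels do not say that the 2 libraries of a genotype came from separate cultures, so the p-values then measure only the spread between these samples.

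The deposited lists held between 11288 peaks (PS_Ca replicate 2) and 47461 peaks (PS_Ia replicate 2). FS_Ca had 24381 ± 10139 peaks, FS_Ia 19999 ± 8709, PS_Ca 21135 ± 13926 and PS_Ia 34022 ± 19006 (SD, n = 2 each). Median peak width lay between 345 bp and 596 bp, and the peaks of a library covered 4.50 to 33.5 Mb. The number of reads is not given in the sources used here. The expected background in the lists, which moves with depth, was lowest in FS_Ia replicate 2 at 0.223 fragments per position and highest in PS_Ia replicate 2 at 0.862 fragments. The lowest called summit was 3 to 5 fragments high, so that a peak missing from the shorter lists was below the threshold there and is not shown to be absent.

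**Figure D1:**
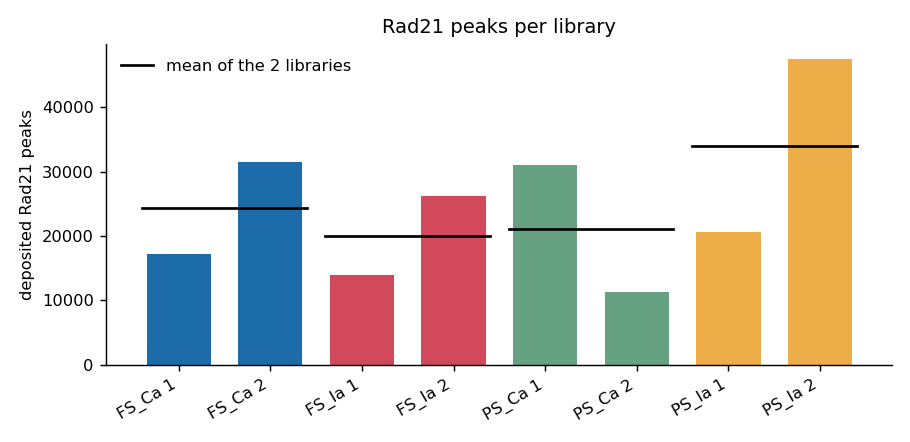
Bars give the number of deposited Rad21 peaks in each of the 8 libraries, coloured by genotype, and black lines the mean of the 2 libraries of a genotype. Within each genotype 1 library held far more peaks than the other. The largest difference was in PS_Ia, with 20582 against 47461 peaks.

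Merging all peaks that overlapped by at least 1 bp gave 64772 regions. Of these, 6747 regions (10.4%) held a peak in all 8 libraries, whatever the allele. These shared regions had a median width of 2022 bp and lay a median of 127 kb apart, with quartiles of 45.8 and 307 kb. The windows of 1 Mb with the most shared regions were on chromosome 1 (positions 85000001 to 86000000, 21 regions), chromosome 11 (3000001 to 4000000, 20 regions) and chromosome 4 (140000001 to 141000000, 18 regions; all coordinates are mm9). At the other end, 34039 regions (52.6%) were found in 1 library only. Of these, 17181 came from PS_Ia replicate 2, the longest list, and between 195 (FS_Ia replicate 1) and 5013 (FS_Ca replicate 2) from each other library. Shared regions were the strong ones: the median percentile rank of their peaks within a list, where 0 is the strongest, was 16.6, against 75.5 for regions of a single library.

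The 10 shared regions with the best ranks were very tall. The first was at chromosome 2, 98506279 to 98507612, with a fold enrichment over background of 237 to 394 and a summit of at least 375 fragments in each of the 8 lists. Beside it were 2 more of the 10, at 98502272 to 98503261 and 98505009 to 98505498. The next in rank were on chromosome 9, at 2999890 to 3008888, 3009126 to 3038420 and 35112702 to 35113296. The remaining 4 were at chromosome 18, 90771435 to 90772031; chromosome 12, 3109751 to 3110242; chromosome 2, 181747197 to 181748087; and chromosome 6, 103598928 to 103599405. No list of repeat-derived segments was used to remove such regions.

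Igh, the edited locus, carried Rad21 in its 3' flank in every library. The flank lies downstream of Cα and holds the 3' regulatory region and the 3' CTCF-binding elements. Its strongest region, at chromosome 12, 114457842 to 114462624, held a peak in all 8 libraries, with a fold enrichment of 7.56 to 18.8 and a summit of 11 to 34 fragments. The neighbouring region at 114453661 to 114456961 was also found in all 8, with folds of 5.04 to 13.1. Another region, farther from Cα, at 114443606 to 114444229, was found in 6 libraries and was missing from FS_Ia replicate 1 and PS_Ca replicate 2, the lists with the fewest peaks. Regions at 114462858 to 114463275 (FS_Ca replicate 2 and PS_Ia replicate 2) and 114463600 to 114464059 (PS_Ca replicate 1 and PS_Ia replicate 2) were found in 2 libraries each. The other 4 regions of the flank were found in 1 library each.

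**Figure D2:**
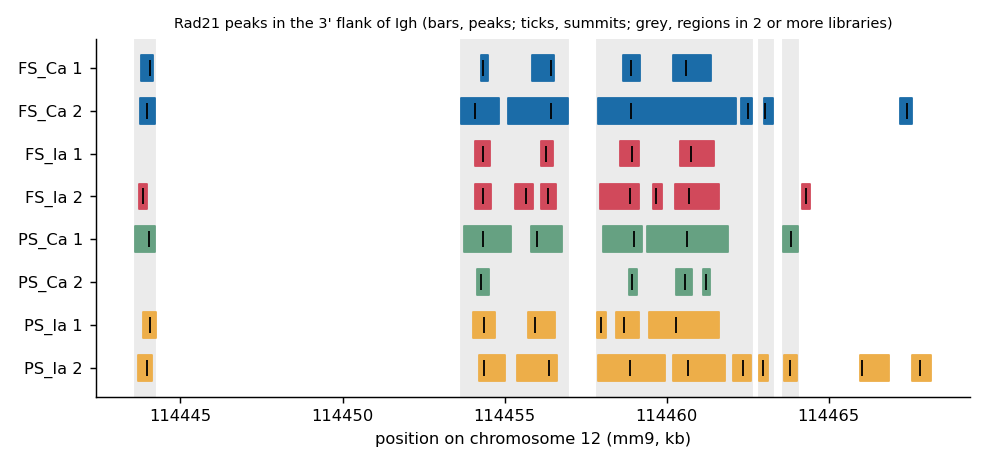
Each line shows the Rad21 peaks of 1 library in the 3' flank of Igh along chromosome 12 (mm9, kb), with summits as ticks; grey bands mark regions found in at least 2 libraries. The bands at 114453661 to 114456961 and 114457842 to 114462624 hold a peak in all 8 libraries.

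The strong flank regions were common to both orientations and both switch lengths. All 4 Ca and all 4 Ia libraries had both of the strong regions, as had all 4 FS and all 4 PS libraries. Over the 9 regions of the flank, the lowest p for presence was 1 against orientation and 0.429 against switch length (Fisher's exact test, two-sided; adjusted p = 1), where 0.0286 is the smallest p that 4 against 4 libraries allow. Farther upstream, the lists had first to be lined up by the offsets given below. Of the 11 lined-up regions from Cμ to the VH genes, the one at 117248843 to 117249696 leaned most to a factor: all 4 PS libraries and 1 FS library (FS_Ia replicate 2) held it (Fisher's exact test, p = 0.143; adjusted over the 20 regions of both parts, p = 1). In the planned mm9 window, Ia libraries held 12.5 ± 7.14 Igh peaks and Ca libraries 11.2 ± 4.03 (SD, n = 4 each), a difference of 1.25 (exact two-sided permutation test, p = 0.829). PS libraries held 13.0 ± 6.48 and FS libraries 10.8 ± 4.79, a difference of 2.25 (exact permutation p = 0.657; p = 0.829 after Benjamini-Hochberg adjustment over the 4 contrasts of peak number, for each of them). Without PS_Ia replicate 2 both differences changed sign, to -1.92 and -0.75, and without PS_Ca replicate 2 the first became -0.167. These counts compare unlike stretches, because the window takes in sequence past the VH genes in the 6 displaced lists, among them all 4 FS lists. In the flank alone, Ia minus Ca was 1.5 peaks (exact permutation p = 0.429) and PS minus FS 0.5 peaks (exact permutation p = 0.857). With Igh lined up, the differences were 0.5 peaks (exact permutation p = 0.971) and 2.5 peaks (exact permutation p = 0.4). The lined-up counts leave out the stretch between the flank and Cμ, where the edited switch regions lie. As deposited, the window of Cα and Sα held 3 peaks in PS_Ia replicate 2 and 1 in FS_Ca replicate 2. Both lists are displaced, so the place of these peaks in Igh was not settled.

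The number of Igh peaks followed the length of the list. Over the 8 libraries Pearson's r was 0.976 (exact permutation p = 0.000248, adjusted over 3 relations 0.000744) and Spearman's rho 0.970 (exact permutation p = 0.000496, adjusted 0.00149). Without the 2 libraries farthest from the median, r was 0.949 (exact permutation p = 0.00278). The other 2 relations of that family did not pass: background against number of peaks (r = 0.642, exact permutation p = 0.0826) and background against Igh peaks (r = 0.642, exact permutation p = 0.0837; adjusted p = 0.0837 for both). Without FS_Ia replicates 1 and 2, the farthest from the median background, these were r = 0.834 (exact permutation p = 0.0389) and r = 0.805 (exact permutation p = 0.0472), unadjusted. In parts that can be compared, list length gave r = 0.922 with the flank peaks and r = 0.896 with the lined-up Igh peaks (exact permutation, adjusted p = 0.00188 for both). Per 10000 peaks, the flank held 2.74 ± 0.430 peaks in Ia and 2.65 ± 0.721 in Ca libraries (SD, n = 4; exact permutation p = 0.8), and 2.63 ± 0.746 in PS and 2.77 ± 0.374 in FS libraries (exact permutation p = 0.743; adjusted p = 0.96 over 6 tests for each). Within the 4 FS libraries, 1 of the sets described below, list length gave r = 0.984 with the Igh peaks (exact permutation p = 0.0833) and r = 0.876 with the flank peaks (exact permutation p = 0.25), where 24 orders allow no p below 0.0417. Background gave r = 0.606 with the number of peaks and r = 0.609 with the Igh peaks there (exact permutation p = 0.375 for both). The other sets, with 2 libraries each, are too small.

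Peaks upstream of Cα cannot be compared by position between all lists. On chromosome 12 beyond the 3' flank, 6 of the 8 libraries had their summits displaced from those of PS_Ia replicate 1 by a constant distance. The displacement was 97.0 kb in both FS_Ca libraries, 99.4 and 99.3 kb in the FS_Ia libraries, 101 kb in PS_Ca replicate 2 and 103 kb in PS_Ia replicate 2, always towards lower positions. PS_Ca replicate 1 was displaced by 0.01 kb. Partners within 500 bp were counted for the shorter of each 2 lists. As deposited, a median of 0% of its summits had one in the 6 displaced libraries, and after the displacement was taken out 76.6%. On chromosome 12 before Igh the best offset was at most 15 bp, and on the other numbered chromosomes at most 22 bp.

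**Figure D3:**
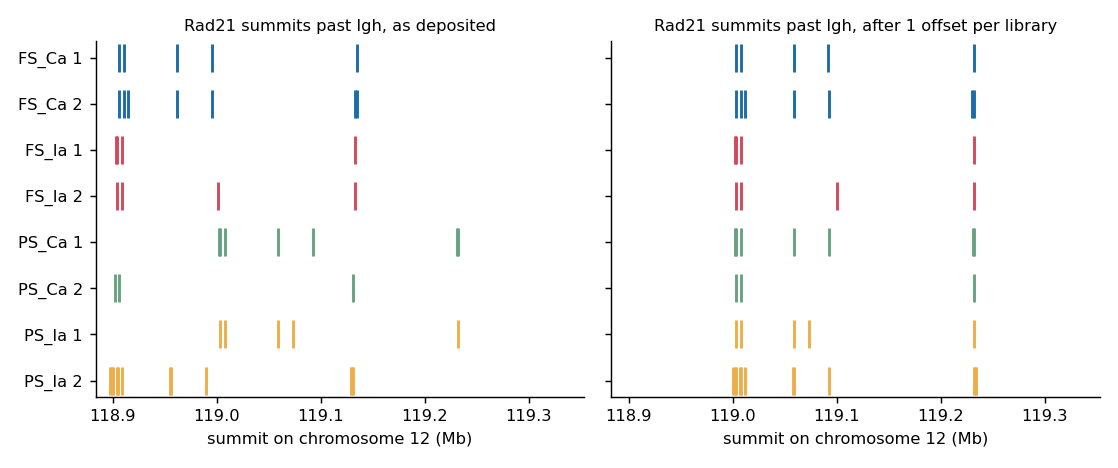
Ticks mark Rad21 summits of the 8 libraries in part of chromosome 12 past Igh (Mb), as deposited on the left and after moving each list by its own offset on the right. On the left 6 libraries are displaced by 97.0 to 103 kb from PS_Ca 1 and PS_Ia 1, and on the right the summits line up.

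The peak names also fell into 3 sets of libraries by prefix: the 4 FS libraries, the replicate 1 libraries of PS_Ca and PS_Ia, and their replicate 2 libraries. Orientation was balanced within each set, whereas switch length was not: no set held both FS and PS libraries, so set and switch length cannot be told apart.

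Orientation was compared over all 8 libraries. Ia libraries had 27010 ± 14534 peaks and Ca libraries 22758 ± 10120 (SD, n = 4 each), a difference of 4252 peaks that was smaller than the spread (exact two-sided permutation test, p = 0.686). The sign did not hold within the sets: Ia minus Ca was -4382.5 peaks in the FS set, -10400 in the replicate 1 set of PS and 36173 in the replicate 2 set of PS. Without PS_Ia replicate 2 the difference was -2565.

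Few regions followed orientation. Of all regions, 15 were found in all 4 Ca libraries and no Ia library, and 16 in all 4 Ia libraries and no Ca library. The strongest Ca-only regions were at chromosome 14, 28620606 to 28622045 (folds 6.21 to 10.8), and chromosome 6, 131513338 to 131514607 (folds 5.78 to 10.2). The strongest Ia-only regions were at chromosome 1, 167050401 to 167051473 (folds 6.16 to 12.4), chromosome 3, 104770761 to 104771402 (folds 6.16 to 13.1), and chromosome 5, 137315565 to 137316608 (folds 6.19 to 10.6). These were peaks of middling rank, with a median percentile of 62.9 for Ca-only and 55.2 for Ia-only regions, and none lay in the Igh window. Past the 3' flank the displaced lists of an orientation could hardly meet as deposited. With each list moved by its offset, 0 regions of chromosome 12 beyond the flank followed orientation. A total of 31 was reached or passed by 22 of the 35 ways to split the 8 libraries into 4 and 4, the real one included. When presence had to come from the strongest 11288 peaks of each library of one side, 2 regions were left, both Ia-only.

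Switch length gave a similar picture. PS libraries had 27578 ± 15505 peaks and FS libraries 22190 ± 8121 (SD, n = 4 each), a difference of 5388.5 peaks (exact two-sided permutation test, p = 0.571), which became -1239 without PS_Ia replicate 2. By switch length, 5 regions were found in all 4 FS libraries and no PS library, and 26 the other way. The strongest PS-only regions were at chromosome 12, 79432791 to 79434073 (folds 5.67 to 11.1), and chromosome 16, 3116203 to 3116575 (folds 5.08 to 11.7). The strongest FS-only region was at chromosome 15, 75012606 to 75013298 (folds 4.91 to 6.46). Again 22 of 35 splits gave a total of 31 or more. In lists of equal size the balance turned, to 25 FS-only and 15 PS-only regions, and none was left when presence had to come from the strongest peaks.

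Between single genotypes, most reproducible regions were common. Of the regions found in both libraries of a genotype (13076 in FS_Ca, 10864 in FS_Ia, 9682 in PS_Ca and 15629 in PS_Ia), FS_Ca and FS_Ia shared 9190, or 84.6% of the smaller number. The shared percentage was 87.1% for PS_Ca and PS_Ia, 85.0% for FS_Ca and PS_Ca, and 86.6% for FS_Ia and PS_Ia. With 2 libraries against 2, p cannot fall below 0.333, so the pairs are described without a test.

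Orientation with full-length switch regions left 1155 regions in both FS_Ca and neither FS_Ia library, and 309 the other way. The first in rank, at chromosome 1, 24618401 to 24623056, was also found in all 4 PS libraries (folds 6.46 to 30.8 over the 6). The second, at chromosome 10, 79371555 to 79371884, was found in FS_Ca alone (folds 6.93 to 18.7). All 5 leading FS_Ia-only regions lay on chromosome 12 upstream of the flank, where positions are displaced, the first at 120609238 to 120609932 in the coordinates of the FS_Ia lists (folds 13.9 to 16.4). After each list was moved by its offset, 5 instead of 32 regions of this part of chromosome 12 separated FS_Ca from FS_Ia. In lists of equal size the counts were 548 and 479. The 2 other splits of these 4 libraries gave 3350 and 887 regions against the 1464 of the genotypes.

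Orientation with partial switch regions left 370 regions in PS_Ca only and 1135 in PS_Ia only. Chromosomes X and 16 stood out. Chromosome X held 181 (48.9%) of the PS_Ca-only regions against 2.60% of all regions, and 176 of the 181 lay in 2 windows, at X 3022301 to 5839670 and X 30280095 to 39910873. Of the 2 libraries, only PS_Ca replicate 2 stood apart on X, with 8.05% of its peaks there, whereas PS_Ca replicate 1, at 2.62%, was within the range of the other 6. Chromosome 16 held 167 (14.7%) of the PS_Ia-only regions against 5.27% of all regions. Leading PS_Ca-only regions were at chromosome 5, 14982165 to 14982502 (folds 7.34 to 13.2; also in FS_Ca replicate 1), and X, 31995671 to 31996232 (folds 8.46 to 10.1). Leading PS_Ia-only regions were at chromosome 13, 83864186 to 83865135 (folds 7.51 to 13.2) and 51512428 to 51514798 (folds 8.51 to 13.1), chromosome 17, 48000964 to 48002171 (folds 6.78 to 13.9), and chromosome 16, 4550706 to 4552062 (folds 7.40 to 12.3). The chromosome 17 region was found in 4 libraries and the others in all 6 outside PS_Ca. The ranks and folds of these PS_Ia-only regions include the FS libraries that held them, so they are not values of PS_Ia alone. Equal-size lists gave 432 and 424 regions, and without chromosomes 16 and X 184 and 955 were left. The 2 other splits gave 5375 and 1060 regions against the 1505 of the genotypes.

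Switch length in the Ca orientation left 448 regions in FS_Ca only and 341 in PS_Ca only. Equal-size lists gave 429 and 389, and the stricter threshold turned the balance to 226 and 310. The same chromosomes stood out: chromosome 16 held 81 (18.1%) of the FS_Ca-only and X 123 (36.1%) of the PS_Ca-only regions. The leading PS_Ca-only region was at chromosome 14, 116958860 to 116960271 (folds 9.45 to 26.0). FS_Ia replicate 2 and PS_Ia replicate 2 also held it, and the folds include theirs. The 2 other splits gave 5115 and 951 regions against the 789 of the genotypes. In the Ia orientation, 181 regions were FS_Ia-only and 2615 PS_Ia-only, and in equal-size lists the counts were 554 and 614. The leading PS_Ia-only region outside chromosome 12 was again chromosome 1, 24618401 to 24623056. The leading FS_Ia-only one outside chromosome 12 was at chromosome 4, 41643930 to 41645494 (folds 6.35 to 24.5). Both FS_Ca libraries and PS_Ca replicate 1 also held it, and the folds include theirs. The 2 other splits gave 4516 and 555 regions against the 2796 of the genotypes.

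Both PS_Ca libraries were low in peaks on chromosome 16. Its share of peaks was 3.10% and 2.81% in PS_Ca, and between 4.68% and 5.67% in the other 6 libraries. In regions found in all 8 libraries, the median summit on chromosome 16 was 0.864 and 0.909 times that on the other numbered chromosomes of the same PS_Ca library (95% bootstrap intervals 0.857 to 0.952 and 0.818 to 0.909). In the other 6 libraries this ratio lay between 1.18 and 1.25. It was the lowest of the numbered chromosomes in both PS_Ca libraries and the highest in each of the other 6.

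**Figure D4:**
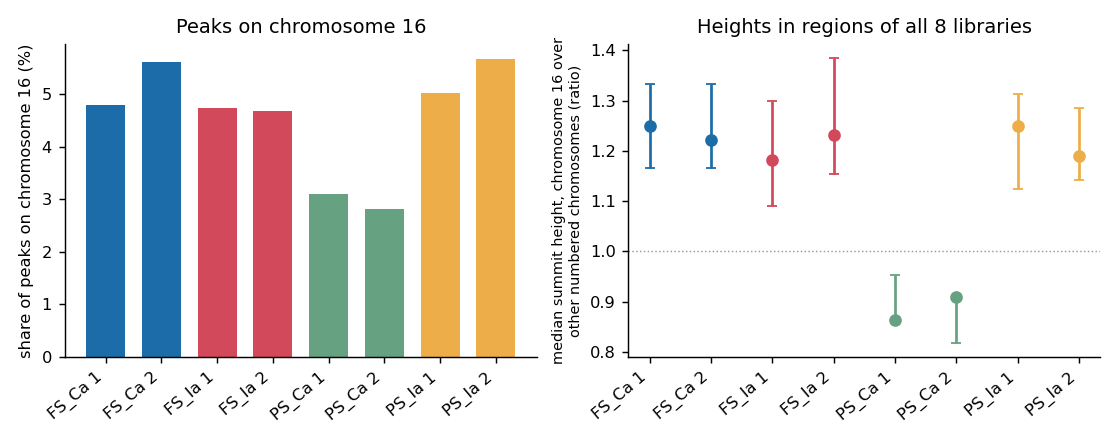
For each library, bars on the left give the share of peaks on chromosome 16 (%), and points on the right the median summit height in chromosome 16 regions over that of the other numbered chromosomes, with 95% bootstrap intervals. Both PS_Ca libraries, at 3.10% and 2.81% and at 0.864 and 0.909, are below the other 6.

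Whether libraries of one genotype shared more regions than others depended on the measure. The Jaccard index, shared regions over the union, averaged 0.382 within and 0.421 between genotypes, a difference of -0.0395 (exact one-sided permutation over all ways to pair the 8 libraries, p = 0.857). In lists of equal size the means were 0.552 and 0.555 (exact permutation p = 0.581). Measured as shared regions over the smaller list, the overlap was 0.853 within and 0.795 between genotypes, the highest of all pairings (exact permutation p = 0.00952, the smallest these pairings can give). The next pairing was close, with a difference of 0.0570 against 0.0587. Within genotypes a short list always met a long one. Among only the 24 pairings that join a shorter with a longer list the mean difference was 0.0431 against 0.0587 for the genotypes (exact permutation p = 0.0417). That is the smallest p these 24 can give, and the next pairing again reached 0.0570. In equal-size lists the difference for the genotypes was -0.00104 (exact permutation p = 0.533).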

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

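Of 28 measures compared over the 8 libraries, 3 had 1 library far from the others; chance alone would give about 1 such measure in 20. PS_Ca replicate 2 had 8.05% of its peaks on chromosome X, against at most 3.44% in the other libraries. It had 6.50% of its peaks on chromosome 2, the lowest share, against at least 6.94% in the others. PS_Ia replicate 2 had 5.69% of its peaks on chromosome 12, against 3.56% to 3.92%. The shares of a list add up to the whole, so the high share of X in PS_Ca replicate 2 lowers its other shares. Its low share of chromosome 2 is therefore not a separate sign. No explanation was tested for the shares of chromosomes 2 and X.

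The share of chromosome 12 in PS_Ia replicate 2 was weighed further because it is the chromosome of the edited locus. A longer list did not account for it: among the 11288 strongest peaks of each library its share of chromosome 12 still exceeded the highest of the other 7 by 0.806 percentage points. In regions found in all 8 libraries, its median summit on chromosome 12 was 1.14 times that of its other numbered chromosomes, and at most 1 in the other 7 libraries, which is consistent with more chromosome 12 fragments in that library. The excess held in 3 of 4 segments along the chromosome, so a gain of the whole chromosome and a change of part of it cannot be told apart. PS_Ia replicate 1 showed no such excess, with a ratio of 0.938.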

How the results depend on the processing

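None of the tested differences in peak number passed the threshold under any setting that gave a test. Their sign turned only where a library was left out, or within sets. Leaving out 1 library moved Ia minus Ca between -2565 and 8642 peaks, PS minus FS between -1239 and 10819 peaks, and the Igh differences between -1.92 and 3.75 and between -0.75 and 4.25. Turned values were -2565, -1239, -1.92 and -0.75 without PS_Ia replicate 2, and -0.167 Igh peaks without PS_Ca replicate 2. Within sets, Ia minus Ca was -10400 in the PS replicate 1 set and -4382.5 in the FS set. For Igh peaks in the planned window it was -3 in the PS replicate 1 set, -3.5 in the FS set and 15 in the PS replicate 2 set. For flank peaks it was 0, 0 and 6 in the same order. With same-numbered libraries as a replicate block the differences were 4252 and 5388.5 peaks and 1.25 and 2.25 Igh peaks (exact sign-flip p = 1, 0.5, 1 and 0.75), and the 31 regions of each factor were reached by 7 of 8 and 5 of 8 splits that part every pair. With 16 sign flips p cannot fall below 0.125, so the block could not bring a difference past 0.05. Same-numbered libraries were not treated as pairs: the correlation of their deviations from the genotype means was 0.0366 for FS_Ca and FS_Ia, 0.127 for PS_Ca and PS_Ia, -0.0690 for FS_Ca and PS_Ca and -0.00771 for FS_Ia and PS_Ia.

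The Jaccard difference turned to 0.0587 as an overlap coefficient, also where only pairings of a shorter with a longer list were used. Part of the 0.0587 came with list length. In equal-size lists the overlap coefficient gave -0.00104 (exact permutation p = 0.533), so no excess within genotypes remained there. Those lists hold only the strongest peaks, so weaker peaks were not compared at equal length. Without 1 library the Jaccard difference lay between -0.0624 and -0.00489.

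Regions of all 8 libraries fell to 4059 under the stricter threshold and 4428 in equal-size lists, which hold fewer peaks. Without 1 library they numbered 6761 to 8494. The stricter threshold gave 969 regions for FS_Ia against FS_Ca, 755 for PS_Ia against PS_Ca and 1588 for PS_Ia against FS_Ia. Equal-size lists gave 856 for PS_Ia against PS_Ca and 1168 for PS_Ia against FS_Ia. Summit-based regions gave 49 for switch length and 1196 for PS_Ca against FS_Ca; the cause was not tested. Strong presence against absence left 2 for orientation, 0 for switch length, and 236, 80, 88 and 236 for FS_Ia against FS_Ca, PS_Ia against PS_Ca, PS_Ca against FS_Ca and PS_Ia against FS_Ia. It turned the balance for PS_Ia against PS_Ca (49 PS_Ca-only, 31 PS_Ia-only) and for PS_Ca against FS_Ca (41 FS_Ca-only, 47 PS_Ca-only).

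With fewer libraries to satisfy, all specific counts rose without 1 library: 53 to 128 for orientation, 52 to 394 for switch length, and 3848 to 11739, 4427 to 23888, 2647 to 10175 and 5732 to 25507 for the 4 pairs in that order. The balance of every pair turned without 1 short list. Without FS_Ia replicate 1 it was 2004 FS_Ca-only to 7453 FS_Ia-only and 5699 FS_Ia-only to 3708 PS_Ia-only. Without PS_Ca replicate 2 it was 6243 PS_Ca-only to 1184 PS_Ia-only and 508 FS_Ca-only to 8302 PS_Ca-only. For switch length it was 40 FS-only to 35 PS-only without FS_Ia replicate 1. The relation of background, the only sign of depth, to number of peaks did not pass over 8 libraries (r = 0.642, exact permutation p = 0.0826) and was r = 0.834 without both FS_Ia libraries (exact permutation p = 0.0389, unadjusted), so the part of depth in these counts is left open. The gene list test, and its alternatives, were not run for lack of an mm9 annotation.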

Other observations

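The test of displaced coordinates, that of new sites beside it, and that of peak number on chromosome 16 were chosen after the result was seen; the other tests in this part were set before their values were computed.

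Beyond the 3' flank of Igh on chromosome 12, Rad21 regions became common once each list was moved by its own offset. In the deposited positions 0 regions of this part held a peak in all 8 libraries, and 9 did afterwards. In the approximate window from Cμ to JH, 3 libraries (FS_Ca replicate 2, PS_Ca replicate 1 and PS_Ia replicate 2) then met in 1 region. It lay at 114662253 to 114663418, with folds of 4.83 to 6.44. In the VH part, a region at 117248843 to 117249696 was found in 5 libraries, all 4 PS and FS_Ia replicate 2, and one at 116446961 to 116448166 in 4, with 2 of each factor level. These positions are those of PS_Ia replicate 1.

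A candidate explanation of the displacement is that 6 lists were made on a reference in which the edited Igh allele replaced that of mm9. With 1 offset per library, a median of 79.2% of the summits of the shorter list found a partner over 7 libraries, PS_Ca replicate 1 without displacement among them. The lowest share was 65.4%, against at most 10% for simulated unrelated lists. Those lists were of equal length with positions drawn evenly, unlike the real ones of 15 to 61 summits, so the 10% is a rough guide. As most summits of each shorter list found a partner, new Rad21 sites do not account for most of the shorter lists. Longer lists have summits without a partner. For PS_Ia replicate 2 the matches were 23 of the 27 summits of the shorter list, so most of its own 61 could not have one. Some of these lay within 500 bp of summits of the undisplaced PS_Ca replicate 1 list. Examples after the offset are 117519419 beside 117519575 and 117887218 beside 117887229. Not all were compared in this way, and what the others are is left open. The 2 PS libraries with displacement lay 4.32 kb (PS_Ca) and 3.46 kb (PS_Ia) beyond the FS libraries of the same orientation, as shorter switch regions would give, which was not tested further. No step recorded in the labels names such a reference.

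The low share of chromosome 16 in PS_Ca was seen in both libraries, from different sets. Fewer peaks do not account for it: each had a smaller share than the library nearest to it in number of peaks, by at least 1.92 percentage points. The higher of the 2 relative summit heights was 0.909, below the lowest of the other 6 libraries at 1.18. Relative to the other 6, chromosome 16 thus gave fewer fragments in PS_Ca. As it was the tallest numbered chromosome in those 6, a loss in PS_Ca and a gain in the others cannot be told apart. Only regions also called in PS_Ca were used, so chromosome 16 sites too weak to be called there did not count. Both PS_Ca libraries were below each of the other 6 in 4 of 4 segments along chromosome 16, from 3122000 to 98028159. A lower copy number of the whole chromosome in this line than in the others may give this. Weaker Rad21 binding along the whole chromosome would give the same values, and no library without precipitation was analysed here. The share of chromosome 16 among regions missing from PS_Ca would follow from either. A low chromosome was also seen in 1 library of a genotype only. In PS_Ia replicate 1 chromosome 15 held 3.78% of peaks, against at least 4.35% in the others and 5.29% in PS_Ia replicate 2. Its relative height there was 0.938, against at least 1 in the others and 1.05 in PS_Ia replicate 2. The cause was not tested.

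The counts of regions specific to an orientation or a switch length do not exclude chance: 22 of 35 splits gave at least 31 regions, for each factor. The highest other split gave 909 regions, 908 of them in FS_Ca replicate 2, FS_Ia replicate 2, PS_Ca replicate 1 and PS_Ia replicate 2, the 4 longest lists. In equal-size lists the highest other split was a different one, with 123 regions. For the Jaccard index, 90 of the pairings gave a difference as large as the -0.0395 of the genotypes, the highest other being 0.0746.

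Peaks on chromosome X in PS_Ca replicate 2 lay mostly in the first 10 Mb and in the window from 30000001 to 40000000, with 382 and 442 of its 909 peaks. FS_Ca replicate 1 had 210 and 213 of 592 there, and PS_Ia replicate 2 had 92 and 78 of 544.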
